A study of Rattus norvegicus with 12 samples.

How the data were processed

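Retinas of 12 rats were sequenced as total RNA, 1 library per rat. The labels put 6 rats in a group injected into the vitreous with 2 µL of PBS and 6 in a group injected with 2 µL of 20 mM NMDA. The libraries are named here by group and the number in their labels, PBS 1 to PBS 6 and NMDA 1 to NMDA 6. The deposited table held 30560 genes with Ensembl rat identifiers, names for all but 6514 of them, their positions, and values for every library. Reads per gene were deposited as whole counts without further scaling, per the file headers and the values. FPKM values were deposited beside them, per the file headers. For 9871 genes with at least 200 counts in every library, FPKM equalled the count divided by 1 gene length and by the library's total count, with a relative spread of that length between libraries of at most 4.09e-06. Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 were named in the submitters' processing notes, without their roles. RSEM estimates are not whole numbers, so the counts were rounded or made in another way before deposit. The genome build, the strand setting and the handling of reads that match several places were not given in the sources used here. Values of near-identical copies, such as the RT1 and haemoglobin genes, and of genes that overlap others are therefore uncertain.

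Total counts ran from 16415611 to 34022023 per library, and 7183 genes had no count in any library. After edgeR's filterByExpr (count minimum 10, total minimum 15), 16260 genes were tested, of which 14416 were protein coding. Counts were scaled by TMM factors between 0.976 and 1.034 and tested with edgeR 4.0.16 (robust quasi-likelihood fit, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The group was the only factor the labels give and the only term of the model. Levels are given as CPM, counts scaled to a common total with the TMM factor, with the SD over 6 libraries, and log2 fold changes (NMDA minus PBS) with their SE from the fit. Adjusted p-values of single genes come from this edgeR test unless another tool is named.

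The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The 37 gene lists were 18 lists of cell type markers and 19 of response programmes. Of their 760 symbols, 715 were found in the table, 6 of them under another name from the rat RefSeq annotation (GRCr8), which served for names alone. The 35 lists with 5 or more tested members were tested with limma 3.58.1 camera (two-sided, on voom log2 CPM, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were run beside it. A list's score in a library was the mean over its tested members of log2 CPM (prior count 2) minus the PBS mean, and NMDA and PBS scores were compared by a two-sided exact permutation test over all 924 assignments.

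The rule named Pou4f1, Rbpms, Thy1, Nefl, Gfap and Aif1 in any case. It added the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1, an informative symbol, and all NMDA libraries on the same side of all PBS libraries. From each list that passed or held 3 or more changed genes it took up to 4 members with the smallest adjusted p. Genes named outside the rule were chosen after their values were seen.

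On simulated counts with 200 changed genes among 16138 tested, made from the means and library sizes of these libraries, the test for NMDA against PBS recovered 62.1% of changes of 0.5 on the log2 scale, 86.6% of changes of 1 and 97% of changes of 2. Of its calls 2.4% were false, and 1 gene was called where nothing was changed. All 3 shifted lists were called, and 0 of 30 lists without shifted genes (limma camera) were. The simulated genes were drawn independently of each other, so that the simulation cannot show how often camera calls lists whose genes vary together. By the recovered shares of changed genes, depth allowed most 2-fold changes of tested genes to be seen, and smaller changes in part.

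Alternatives replaced TMM with DESeq2 size factors or with library size only, removed or tightened the filter (10 CPM in 6 libraries), left out each library, added the replicate number as a block, took out lens crystallin, haemoglobin and mitochondrial genes, or added a lens marker score as a covariate. Others used the DESeq2 1.42.0 Wald test, limma voom with quality weights, limma trend on log2(FPKM + 1) and log2(FPKM + 0.1), and camera on ranks. A melanin gene covariate, a fit without PBS 5 and NMDA 3, and the permutation of list scores were added after the data were seen. Nothing in the labels says that equal numbers mark the same litter or day. No pair of libraries in a group had the same counts, and reads were not aligned anew, since only the deposited table was used here.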

Results

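Total RNA was sequenced from the retinas of 12 rats, 6 injected into the vitreous with PBS and 6 with NMDA, an agonist of a class of glutamate receptors that injures retinal neurons by overstimulation and serves as a model of the ganglion cell damage in glaucoma. The time between injection and collection was not given in the sources used here. Total counts of PBS 1 to PBS 6 were 31057161, 25990898, 16415611, 27920667, 25457609 and 27774301, and those of NMDA 1 to NMDA 6 were 26298655, 27716698, 34022023, 26769796, 29391258 and 27982472. A two-sided exact permutation test of the group means gave p = 0.277 (n = 6 each). Mitochondrially encoded genes took 4.37% ± 0.0899 of the counts with PBS and 3.996% ± 0.214 with NMDA (SD, n = 6; two-sided exact permutation p = 0.00866). Lens crystallin genes took 0.011% to 0.391% per library, lowest in NMDA 1. The first principal component held 44.7% of the variance and had all PBS libraries below 0 and all NMDA libraries above 0. NMDA 1 and NMDA 3 stood at opposite ends of the second component, at 62.2 and -32.5 (15.7% of the variance).

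The comparison of NMDA with PBS asked which retinal transcripts differ after the excitotoxic injection. Of 19 ganglion cell markers 18 fell, and of 31 interferon response genes 29 rose (limma camera, two-sided, adjusted p = 3.58e-11 and 1.62e-11; adjusted p = 0.307 for both with an estimated correlation). Of 16260 genes tested, 6167 changed (37.9%; edgeR), 3315 higher and 2852 lower. At least 2-fold changes were found in 984 genes, 744 higher and 240 lower, and 207 genes rose at least 4-fold. Without NMDA 3, 736 genes were at least 2-fold higher and 364 lower. In 2942 genes (18.1%) all NMDA libraries lay on 1 side of all PBS libraries, against 0.216% by chance. With scaling by library size only, 4233 genes were higher and 2323 lower, a share of 64.6% higher against 53.8% with TMM. The median log2 fold change of all genes was 0.06 with that scaling and 0.01 with TMM.

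**Figure D1:**
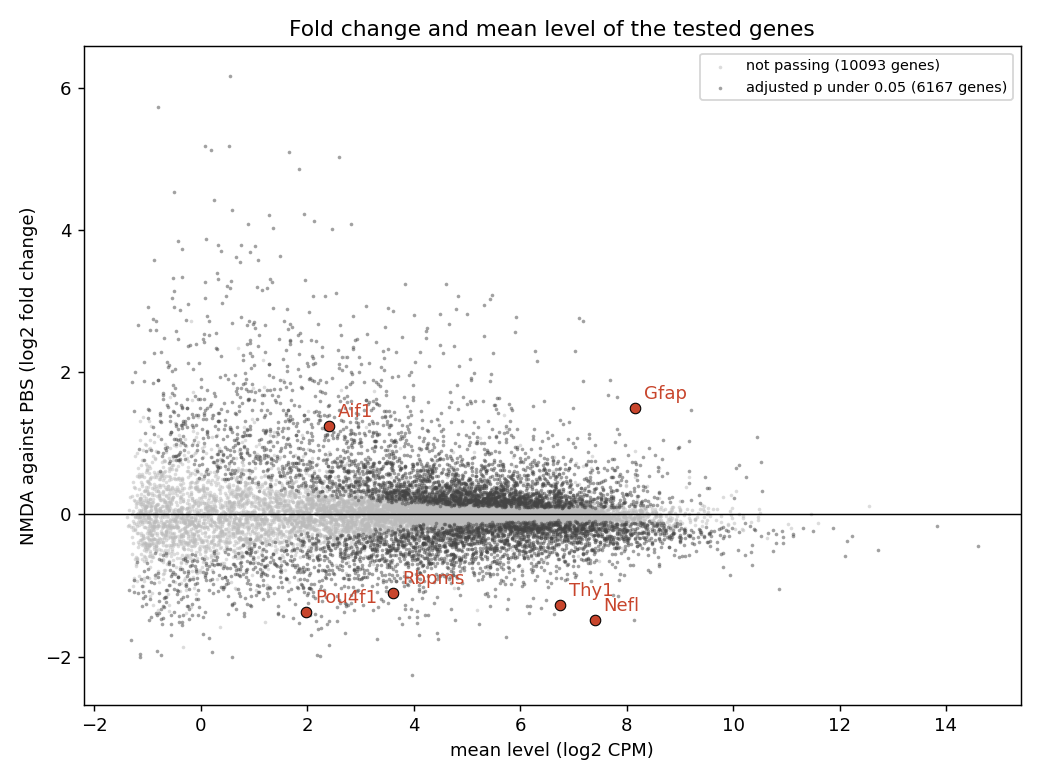
Each point is 1 of the 16260 tested genes, with its mean level (log2 CPM) across and its log2 fold change, NMDA against PBS, upward. Dark points are the 6167 genes with an adjusted p under 0.05, and the 6 genes fixed in advance are labelled, of which Rbpms did not pass.

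Genes that mark ganglion cells, whose axons form the optic nerve, fell after NMDA. Thy1, which encodes a surface glycoprotein (ENSRNOG00000006604, chromosome 8, 44389513 to 44394659), fell from 153 ± 9.46 to 63.1 ± 24.2 CPM (SD, n = 6 each), a log2 fold change of -1.28 ± 0.21 (SE; edgeR adjusted p = 0.000645). Nefl, the light neurofilament gene (ENSRNOG00000013658, chromosome 15, 42301916 to 42305793), fell from 249 ± 17.5 to 89.0 ± 40.7 CPM (-1.48 ± 0.25, edgeR adjusted p = 0.000872). Pou4f1, a transcription factor gene of these cells (ENSRNOG00000060662, chromosome 15, 81257781 to 81259728), fell from 5.61 ± 0.833 to 2.16 ± 1.41 CPM (-1.37 ± 0.34, edgeR adjusted p = 0.00677). In each of these 3 genes all NMDA libraries lay below all PBS libraries. Rbpms, an RNA-binding protein gene (ENSRNOG00000013328, chromosome 16, 58239474 to 58395426), had 16.6 ± 6.61 CPM with PBS and 7.76 ± 7.64 with NMDA and did not pass (-1.10 ± 0.56, edgeR adjusted p = 0.148). Without NMDA 3 its log2 fold change was -1.71 and passed (adjusted p = 0.0175). Positions are those in the deposited table, whose genome build was not given in the sources used here.

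Glial and microglial genes of the fixed set rose. Gfap, an intermediate filament gene switched on in stressed retinal glia (ENSRNOG00000002919, chromosome 10, 87852890 to 87861589), rose from 150 ± 65.0 to 424 ± 181 CPM (SD, n = 6 each; 1.50 ± 0.35, edgeR adjusted p = 0.00558). Aif1, which encodes the microglial protein IBA1 (ENSRNOG00000000853, chromosome 20, 3646777 to 3652668), rose from 3.13 ± 1.00 to 7.34 ± 1.94 CPM (1.24 ± 0.23, edgeR adjusted p = 0.00101). All NMDA libraries lay above all PBS libraries for both genes.

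Among the 10 largest rises by the rule, Msr1 belonged to the microglia and macrophage list and Bcl2a1 to the cell death list. Hk3, a hexokinase gene of white blood cells (ENSRNOG00000026235, chromosome 17, 9599865 to 9614863), rose 29.1-fold, from 0.211 ± 0.204 to 6.67 ± 3.50 CPM (SD, n = 6 each; edgeR adjusted p = 8.11e-05). Siglec1, a macrophage lectin gene, rose 18.6-fold (log2 fold change 4.22, and 4.95 without PBS 5), Lilrb4, an inhibitory receptor gene, 17.5-fold, and Msr1, a scavenger receptor gene, 17.0-fold. Ly6c, a gene of monocyte surface antigens, rose 12.4-fold, and Bcl2a1, an anti-apoptotic gene, 11.97-fold. Pla2g7, Clec7a and Clec4a1, genes of a secreted phospholipase and of lectin receptors, rose 9.90-, 9.83- and 9.67-fold.

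The 10 largest falls by the rule held 3 members of the ganglion cell list (Slc17a6, Nrn1 and Pou4f2), 1 of the amacrine list (Slc17a8) and 1 of the pigment epithelium list (Rpe65). Hhatl, a membrane protein gene (ENSRNOG00000019404, chromosome 8, 121447002 to 121454001), fell from 26.0 ± 6.90 to 5.44 ± 2.60 CPM (SD, n = 6 each; -2.25 ± 0.31, edgeR adjusted p = 0.000251). Slc17a8 and Slc17a6, vesicular glutamate transporter genes of amacrine and ganglion cells, had log2 fold changes of -1.99 and -1.72. Pou4f2, a ganglion cell transcription factor gene, was at -1.60, Irx4, a homeobox gene, at -1.61, and Nrn1, the neuritin gene, at -1.67. Cpne4, a copine gene, was at -1.69, and Egfl6 and Hmcn2, genes of extracellular matrix proteins, were at -1.97 and -1.75. Rpe65, the isomerase gene of the visual cycle, fell by 1.67 on the log2 scale (SE 0.31; edgeR adjusted p = 0.00119).

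Of the 37 lists fixed in advance, 35 had enough tested members for camera and 23 passed (limma camera, two-sided), 12 higher and 11 lower. None passed camera with an estimated correlation, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.307, and 26 passed fry. By the score in each library, 29 of 37 lists passed the two-sided exact permutation test after adjustment, whose smallest possible p was 0.00217. Other splits of the same libraries into 6 and 6 gave up to 28 passing lists with camera. The split with 28 kept 4 PBS libraries together, and thus part of the difference between the groups. The median over the other splits drawn was 15 passing lists, and a split with 3 PBS libraries on each side gave 22. Camera with the preset correlation thus passed many lists without the contrast of NMDA with PBS. A pass of this camera alone therefore does not show that a list differs between the groups. The splits neither excluded chance for the count of 23 lists nor showed that chance gives that many. In 13 of these 23 lists the score of NMDA 1 lay beyond the PBS range, against 19 to 22 for each other NMDA library.

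**Figure D2:**
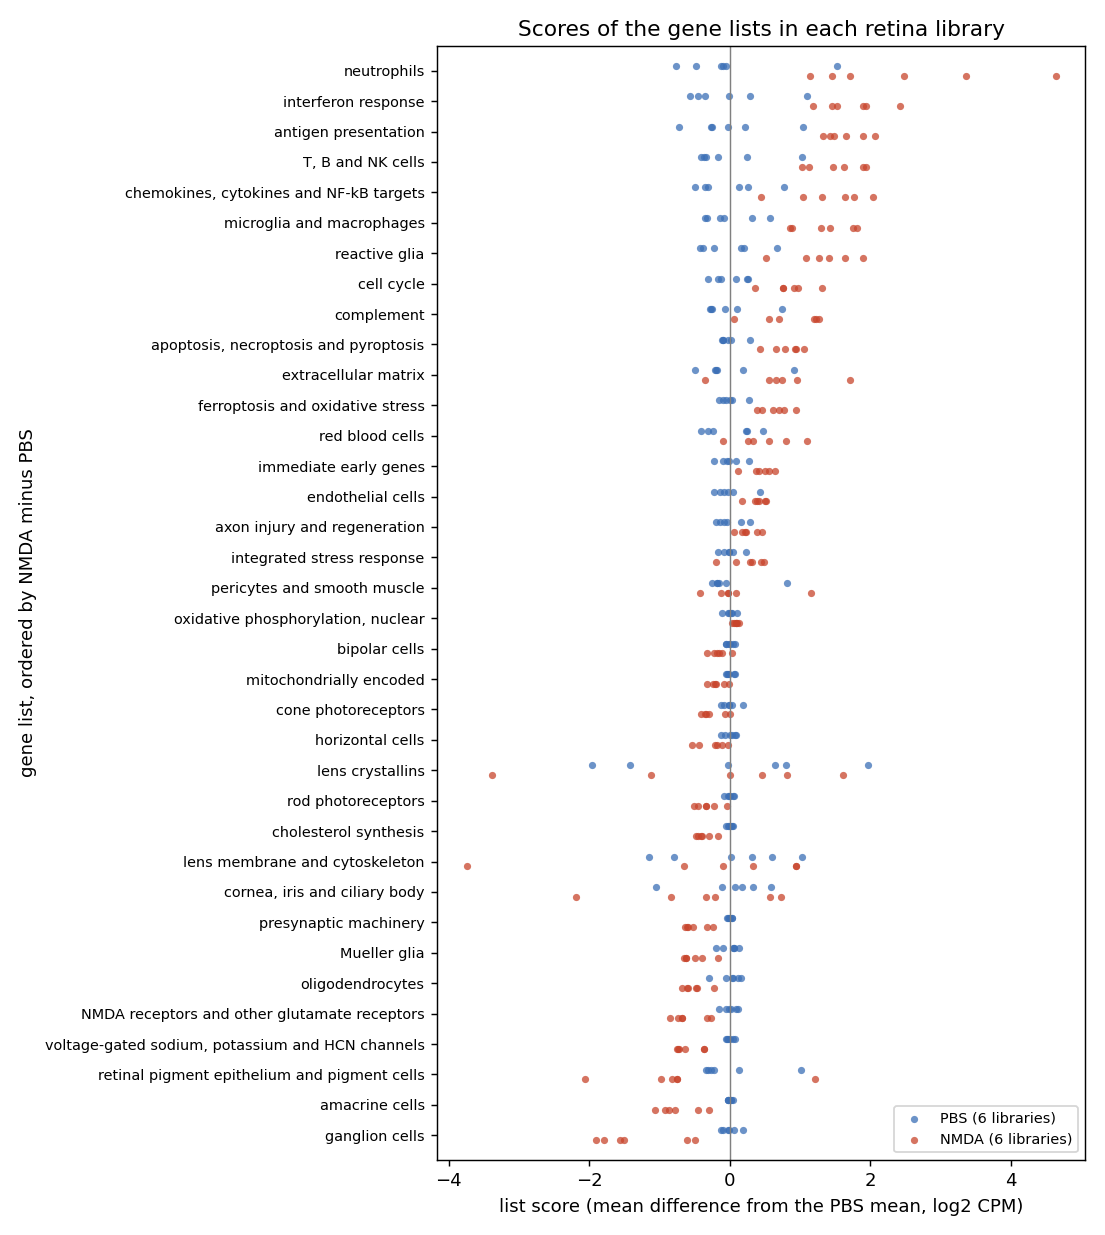
Scores of 36 of the 37 gene lists in each library (mean difference of log2 CPM from the PBS mean), with PBS and NMDA libraries as points. The ganglion cell scores of NMDA 1 (-0.61) and NMDA 3 (-0.49) lie nearest to PBS, and the other NMDA libraries lie between -1.50 and -1.91.

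Of 19 measured ganglion cell markers, 18 fell and none rose (18 adjusted over the list alone), with a median log2 fold change of -1.28. Stmn2, a microtubule regulator gene, Chrna6, a nicotinic receptor gene, Ebf3, a transcription factor gene, and Nefh, the heavy neurofilament gene, fell by 0.93, 0.91, 0.76 and 0.79 on the log2 scale. The list passed limma camera (adjusted p = 3.58e-11) and had an adjusted p = 0.307 with an estimated correlation. Its score was lower in all NMDA libraries than in all PBS libraries, by 1.31 on average (two-sided exact permutation p = 0.00217, the smallest possible). NMDA 1 and NMDA 3, which stood apart on the second principal component, had the ganglion scores nearest to PBS, -0.61 and -0.49.

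Amacrine cells, the inhibitory interneurons of the inner retina, had 17 of 19 markers lower (18 adjusted over the list alone), with a median of -0.50. Th, the tyrosine hydroxylase gene of dopaminergic amacrine cells, fell from 8.64 ± 0.733 to 3.06 ± 0.961 CPM (SD, n = 6; -1.50 ± 0.17, edgeR adjusted p = 6.40e-05). Gad2, the GABA-producing decarboxylase gene, and Slc32a1, the vesicular inhibitory transporter gene, fell by 0.53 and 0.50 on the log2 scale. Among members chosen after their values were seen, Calb2, the calretinin gene, fell by 1.48 and Chat, of cholinergic cells, by 1.18. The deposited annotation gives Chat the type pseudogene. The amacrine list passed camera (adjusted p = 6.43e-09; adjusted p = 0.307 with an estimated correlation).

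Bipolar cells, which carry photoreceptor signals inward, had 6 of 17 markers lower and 1 higher (the same counts adjusted over the list alone; median -0.15). Prkca, of rod bipolar cells, fell by 0.35, Bhlhe22, a transcription factor gene, by 0.43 and Ca8, a carbonic anhydrase-related gene, by 0.49, and Grik1, a kainate receptor gene, rose by 0.24 (log2). These markers passed camera as a list (adjusted p = 0.0115; adjusted p = 0.371 with an estimated correlation), with NMDA 1 (0.03) within the PBS range of scores. Of 7 horizontal cell markers, Calb1, the calbindin gene, and Gja10, a connexin gene, both chosen after their values were seen, fell by 0.47 and 0.50. The call of Gja10 ended without PBS 5 and NMDA 3 together (adjusted p = 0.0634). That list did not pass camera (adjusted p = 0.0922), and it passed fry (adjusted p = 0.0158).

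Rods, the photoreceptors of dim light, had 15 of 20 markers lower (16 adjusted over the list alone), with a median of -0.31. Rom1 and Prph2, outer segment membrane protein genes, fell by 0.51 and 0.38, Pde6b, a phototransduction phosphodiesterase gene, by 0.40, and Slc24a1, a cation exchanger gene, by 0.48. Of 12 cone markers, 6 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.25). Grk1, a photoreceptor kinase gene, fell by 0.57, Opn1mw, the middle-wavelength opsin gene, by 0.67, Arr3, the cone arrestin gene, by 0.70, and Thrb, a thyroid hormone receptor gene, by 0.20. Gnb3, a cone and bipolar G protein gene chosen after its values were seen, rose by 0.78. The rod and cone lists passed camera (adjusted p = 1.28e-05 and 0.00496), with adjusted p = 0.341 for both with an estimated correlation. Within the PBS range lay the rod score of NMDA 1 (-0.03) and the cone scores of NMDA 1 (0.01) and NMDA 2 (-0.07).

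Müller glia, the main support cells of the retina, had lower levels of most marker genes. Of 16 markers, 9 fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.50. Rlbp1, the retinaldehyde-binding protein gene, fell from 317 ± 39.9 to 144 ± 31.7 CPM, and Glul, the glutamine synthetase gene, from 2528 ± 524 to 1220 ± 190 CPM (SD, n = 6; log2 fold changes -1.14 and -1.05). Dkk3, a secreted Wnt modulator gene, fell by 0.71. Sox2, a progenitor transcription factor gene, rose by 0.75, and Sox9, chosen after its values were seen, by 0.23. As a list they passed camera (adjusted p = 0.00429; adjusted p = 0.307 with an estimated correlation), with NMDA 3 (-0.16) within the PBS range of scores.

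Reactive glia genes rose: 20 of 30 (24 adjusted over the list alone) and none fell, with a median of 1.15. S100a10, a calcium-binding protein gene, rose from 18.5 ± 1.46 to 67.5 ± 13.8 CPM (SD, n = 6; 1.87 ± 0.13, edgeR adjusted p = 5.04e-06). Vim, the vimentin gene, rose by 1.46, Osmr, a cytokine receptor gene, by 1.96 and Gbp2, a guanylate-binding protein gene that the interferon list also holds, by 3.07 (log2). The list passed camera (adjusted p = 2.78e-08; adjusted p = 0.309 with an estimated correlation), and its score in PBS 5 (0.67) lay above that in NMDA 1 (0.51).

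Microglia and macrophage genes rose in 18 of 25 members and fell in 1 (19 and 1 adjusted over the list alone), with a median of 1.16. Cx3cr1, the fractalkine receptor gene, rose from 9.28 ± 0.937 to 20.7 ± 3.82 CPM (SD, n = 6; 1.16 ± 0.12, edgeR adjusted p = 3.54e-05). Tyrobp, a signalling adaptor gene, rose by 2.31, Cd14, a bacterial product receptor gene, by 3.07 and Cd68, a lysosomal protein gene, by 2.85 (log2). P2ry12, a purine receptor gene of resting microglia, was the 1 that fell, by 0.52, and was chosen after its values were seen. The list passed camera (adjusted p = 5.40e-07; adjusted p = 0.307 with an estimated correlation).

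Genes of other white blood cells had low counts. All 3 tested neutrophil genes rose, Mmp9, a matrix protease gene, from 1.15 ± 0.775 to 4.23 ± 2.21 CPM, Csf3r, a growth factor receptor gene, from 1.21 ± 0.778 to 7.79 ± 9.01, and S100a9, a calprotectin gene, from 0.185 ± 0.346 to 3.29 ± 5.18 (SD, n = 6; edgeR adjusted p = 0.0103, 0.0132 and 0.0207). Without NMDA 6 the log2 fold change of S100a9 was 2.66 in place of 4.08 and did not pass (adjusted p = 0.0552), and without PBS 5 it was 5.81. For Csf3r it was 1.84 without NMDA 6 in place of 2.69, and passed (adjusted p = 0.0269). Of 4 tested lymphocyte genes, Cd8a, a T cell co-receptor gene, rose from 0.0772 ± 0.123 to 2.63 ± 1.60 CPM (SD, n = 6; edgeR adjusted p = 0.000421), with a log2 fold change of 5.19, and of 6.50 without PBS 5. Cd3e, of the T cell receptor complex, rose from 0.137 ± 0.189 to 0.551 ± 0.317 CPM (SD, n = 6; edgeR adjusted p = 0.0228). The call of Cd3e ended without PBS 1, PBS 2, PBS 4, PBS 6 or NMDA 6 (adjusted p up to 0.0560), and without PBS 5 its log2 fold change was 3.20 in place of 2.01. Lck, a T cell kinase gene, did not pass (0.63, edgeR adjusted p = 0.0891) and passed without PBS 5 or NMDA 2 (lowest adjusted p = 0.0360). Both lists held too few tested members for camera. Adjusted over the list alone, 3 neutrophil genes and 3 lymphocyte genes rose and 1 lymphocyte gene fell.

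Interferon response genes rose in 29 of 31 members (30 adjusted over the list alone), with a median of 1.61. Bst2, the tetherin gene, rose from 5.41 ± 2.63 to 32.0 ± 10.3 CPM (SD, n = 6; 2.58 ± 0.32, edgeR adjusted p = 0.000165). Psmb9, an immunoproteasome gene, rose by 1.97, Stat2, a signal transducer gene, by 0.59 and Herc6, a ubiquitin ligase gene, by 0.63 (log2). Antigen presentation genes rose in 16 of 19 and fell in 1 (17 and 1 adjusted over the list alone; median 1.81). B2m, the invariant chain gene of class I molecules, rose from 95.2 ± 26.6 to 305 ± 64.5 CPM (SD, n = 6; 1.68 ± 0.19, edgeR adjusted p = 8.42e-05), and the class II loading genes RT1-DMb and RT1-DMa rose by 1.86 and 1.50. Ciita, the class II transactivator gene, fell by 0.69 and was chosen after its values were seen. The interferon and antigen presentation lists passed camera (adjusted p = 1.62e-11 and 1.87e-07), with adjusted p = 0.307 for both with an estimated correlation. PBS 5 had the highest interferon score of the PBS libraries, 1.09, and NMDA 2 the lowest of the NMDA libraries, 1.19.

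Complement genes rose in 8 of 17 members (8 adjusted over the list alone), with a median of 0.84. C3ar1, a complement receptor gene, rose by 2.23, C1r and C1s, genes of proteases of the first component, by 1.53 and 1.55, and C1qc, a recognition subunit gene, by 1.04 (log2). The complement score of PBS 5 (0.75) lay above those of NMDA 1, NMDA 2 and NMDA 4 (0.05, 0.56 and 0.71), all 3 within the PBS range. Chemokine, cytokine and NF-kB genes rose in 16 of 23 and fell in 1 (17 and 1 adjusted over the list alone; median 1.30). Ccl2, a monocyte chemoattractant gene, rose from 0.613 ± 0.437 to 10.1 ± 6.65 CPM (SD, n = 6; 4.02 ± 0.65, edgeR adjusted p = 0.000603). Il1rn, an interleukin antagonist gene, rose by 2.47, Cxcl16, a chemokine gene, by 1.45 and Nfkb2, a transcription factor gene, by 1.17. Tnfaip3, a brake on NF-kB signalling chosen after its values were seen, fell by 0.52 (edgeR adjusted p = 0.0495). That call held only in the fits without PBS 5, PBS 6, NMDA 3 or NMDA 4 of the 12 fits without 1 library (adjusted p up to 0.0967), and ended with library size only, in limma and with no filter on low counts, among others. The complement and chemokine lists passed camera (adjusted p = 0.00178 and 2.19e-05), with adjusted p = 0.396 and 0.359 with an estimated correlation, and the chemokine score of PBS 5 (0.77) lay above that of NMDA 1 (0.44).

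Endothelial genes rose in 6 of 13 members (6 adjusted over the list alone; median 0.43), among them Eng, the endoglin gene, by 1.05, Flt1, a VEGF receptor gene, by 0.60, Emcn, the endomucin gene, by 0.55 and Pecam1, an adhesion molecule gene, by 0.47 (log2). That list passed camera (adjusted p = 0.00943; adjusted p = 0.359 with an estimated correlation), and PBS 5 (0.43) had a higher score than NMDA 1, NMDA 2, NMDA 5 and NMDA 6 (0.42, 0.36, 0.18 and 0.39). Of 11 pericyte genes, Cspg4, a proteoglycan gene, rose by 0.75 and Rgs5, a G protein regulator gene, fell by 0.61, and the list did not pass (adjusted p = 0.530). Both were chosen after their values were seen, and Rgs5 did not pass adjusted over the list alone. The call of Rgs5 held only in the fits without NMDA 1 or NMDA 3 of the 12 fits without 1 library (adjusted p up to 0.102), and ended with library size only, with no filter on low counts, with the replicate number as a block and with a lens marker covariate.

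Oligodendrocyte genes fell in 3 of 6 members (3 lower and 1 higher adjusted over the list alone), Ermn by 1.03, Mag by 1.49 and Mbp by 0.62 (log2), genes of myelin proteins. The list did not pass camera (adjusted p = 0.147), and it passed fry (adjusted p = 0.00859). No member of the lists for red blood cells (5 tested), lens crystallins (15) and cornea, iris and ciliary body (9) passed, and these lists had adjusted p = 0.124, 0.592 and 0.751. The red blood cell list passed without NMDA 2 (adjusted p = 0.0431). In the lens membrane list 1 of 10 genes fell, Hspb6, a small heat shock protein gene, by 0.32, chosen after its values were seen (list adjusted p = 0.367). NMDA 1 had a lens membrane score of -3.74, far below the others.

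Genes of the pigment epithelium fell in 4 of 12 members (4 adjusted over the list alone), all of the visual cycle or retinoid transport: Rpe65, Rgr, an opsin gene, by 1.36, Ttr, the transthyretin gene, by 1.14 and Lrat, an acyltransferase gene, by 0.98 (log2). The call of Lrat (edgeR adjusted p = 0.0303) ended without PBS 3, NMDA 2, NMDA 4 or NMDA 5 (adjusted p up to 0.0712). The list had a median of 0.02 and a lower direction in camera without passing (adjusted p = 0.0552). It passed with scaling by library size only (adjusted p = 0.0187, median 0.07) and without PBS 1, PBS 2, PBS 4, PBS 6 or NMDA 3 (adjusted p = 0.0476, 0.0421, 0.0449, 0.0355 and 0.00392). Its score was highest in PBS 5 (1.02) and NMDA 3 (1.22) within their groups and lowest in NMDA 1 (-2.06).

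Genes of glutamate receptors, the targets of the injected agonist among them, fell in 20 of 22 members (20 adjusted over the list alone), with a median of -0.53. Grin1, the obligatory NMDA receptor subunit gene, fell from 183 ± 12.7 to 119 ± 17.6 CPM (SD, n = 6; -0.62 ± 0.09, edgeR adjusted p = 0.000219). Grin2c, another NMDA receptor subunit gene, fell by 0.86, and the AMPA receptor genes Gria4 and Gria1 by 0.56 and 0.42 (log2). Genes of the presynaptic machinery fell in 20 of 21 (20 adjusted over the list alone; median -0.35), with Sv2a, a vesicle glycoprotein gene, at -0.48, Cplx2, a complexin gene, at -0.87, Vamp2, a fusion protein gene, at -0.34 and Rims2, an active zone gene, at -0.30. Voltage-gated channel genes fell in 21 of 22 (21 adjusted over the list alone; median -0.58), with the sodium channel genes Scn1a at -0.58 and Scn2b at -0.71 and the potassium channel genes Kcnq3 at -0.90 and Kcna1 at -0.62. The 3 lists passed camera (adjusted p = 3.94e-09, 6.53e-11 and 1.62e-11), with adjusted p = 0.307 for each with an estimated correlation.

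Cell death genes rose in 22 of 31 members and fell in 1 (23 and 1 adjusted over the list alone; median 0.72). Ripk3, a necroptosis kinase gene, rose from 0.712 ± 0.359 to 5.22 ± 2.85 CPM (SD, n = 6; 2.88 ± 0.40, edgeR adjusted p = 0.000205), Pycard, an inflammasome adaptor gene, by 2.18 and Bak1, a pro-apoptotic gene, by 0.95 (log2). Bcl2a1 of this list counters apoptosis and rose by 3.58. Bmf, a pro-apoptotic gene chosen after its values were seen, fell by 0.37. Ferroptosis and oxidative stress genes rose in 13 of 29 and fell in 2 (14 and 2 adjusted over the list alone; median 0.42). Cyba and Ncf1, genes of the phagocyte oxidase, rose by 1.38 and 2.04, and Hmox1, the haem oxygenase gene, by 2.80. Mt3, a metallothionein gene, and Sqstm1, an autophagy receptor gene, fell by 1.27 and 0.20 and were chosen after their values were seen. Both lists passed camera (adjusted p = 4.49e-06 and 0.00114), with adjusted p = 0.307 for both with an estimated correlation.

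Injury and stress programmes were mixed. Of 20 axon injury genes, 7 rose and 5 fell (9 and 5 adjusted over the list alone; median 0.13). Gap43, a growth cone gene, rose from 26.1 ± 3.06 to 70.2 ± 14.8 CPM (SD, n = 6; 1.42 ± 0.14, edgeR adjusted p = 2.46e-05), Jun, an injury transcription factor gene, by 0.67, Csrp1, a cytoskeletal gene, by 0.77 and Ecel1, a peptidase gene of injured neurons, by 0.95 (log2). The axon survival gene Nmnat2 fell by 0.69, the injury kinase gene Map3k12 by 0.19, the axon degeneration gene Sarm1 by 0.18, the calcium channel subunit gene Cacna2d1 by 0.30 and the microtubule regulator gene Stmn4 by 0.25, all chosen after their values were seen. Leaving out PBS 1 or PBS 2 ended the calls of Sarm1, Cacna2d1 and Stmn4 (adjusted p up to 0.0571, 0.0788 and 0.0717 over the fits without 1 library). The call of Sarm1 also ended without PBS 4, NMDA 5 or NMDA 6, that of Cacna2d1 without PBS 5, PBS 6, NMDA 2, NMDA 4, NMDA 5 or NMDA 6, and that of Stmn4 without PBS 5, PBS 6, NMDA 2 or NMDA 4. Scaling by library size only gave 8 higher and 2 lower, and in it and in limma trend on FPKM these 3 genes did not pass either, nor did Sarm1 without PBS 5 and NMDA 3 together or Stmn4 with the replicate number as a block. The list did not pass camera (adjusted p = 0.459), and its score was higher with NMDA (0.25; two-sided exact permutation adjusted p = 0.0387).

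Of 24 genes of the integrated stress response, 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.11). Phgdh, a serine synthesis gene, rose by 1.00, and Atf5 and Atf3, stress transcription factor genes, by 0.94 and 1.28, whereas Ddit4, an inhibitor of mTOR signalling, fell by 0.27 and Ppp1r15a, a phosphatase subunit gene chosen after its values were seen, by 0.25 (log2). The list did not pass camera (adjusted p = 0.430).

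Immediate early genes rose in 10 of 25 members and fell in 1 (10 and 2 adjusted over the list alone; median 0.11). Myc rose from 1.02 ± 0.527 to 5.88 ± 2.08 CPM (SD, n = 6; 2.52 ± 0.35, edgeR adjusted p = 0.000206), Fos and Fosl1, genes of AP-1 subunits, by 1.07 and 1.31 and Dusp5, a phosphatase gene, by 0.59 (log2). Npas4, a neuronal activity gene chosen after its values were seen, fell by 1.33 (edgeR adjusted p = 0.0174), and did not pass with the replicate number as a block (adjusted p = 0.0800). Cell cycle genes rose in 14 of 21 (17 adjusted over the list alone; median 0.83). Ccnd1, the cyclin D1 gene, rose from 9.46 ± 2.65 to 76.9 ± 27.0 CPM (SD, n = 6; 3.02 ± 0.26, edgeR adjusted p = 2.01e-05), and the replication genes Mcm6, Mcm3 and Pcna by 0.64, 1.12 and 0.34. Both lists passed camera (adjusted p = 0.00956 and 8.05e-06), with adjusted p = 0.371 and 0.307 with an estimated correlation, and the immediate early score of NMDA 1 (0.12) lay within the PBS range.

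Extracellular matrix genes rose in 11 of 32 members and fell in 1 (11 and 1 adjusted over the list alone; median 0.63). Lgals3, the galectin gene of phagocytes, rose from 6.53 ± 3.52 to 48.4 ± 22.0 CPM (SD, n = 6; 2.89 ± 0.38, edgeR adjusted p = 0.000215), Fn1, the fibronectin gene, by 2.29, Tgfbi, a matrix protein gene, by 2.11 and Mmp14, a matrix protease gene, by 0.69 (log2). Lox, a collagen cross-linking gene chosen after its values were seen, fell by 0.95. The list passed camera (adjusted p = 0.0153; adjusted p = 0.546 with an estimated correlation). It did not pass without NMDA 3 (adjusted p = 0.117), with library size only (0.0703), by fry (0.0836) or by the exact permutation of its score (0.0801), which was higher in PBS 5 (0.91) than in NMDA 1, NMDA 2, NMDA 4 and NMDA 5 (-0.36, 0.66, 0.55 and 0.74).

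Cholesterol synthesis genes fell in 15 of 19 members (15 adjusted over the list alone; median -0.35). Insig1, a sterol sensor partner gene, fell from 97.6 ± 4.20 to 60.1 ± 8.43 CPM (SD, n = 6; -0.70 ± 0.08, edgeR adjusted p = 5.88e-05), Fdft1, the squalene synthase gene, by 0.48 and Stard4, a sterol transfer gene, by 0.42 (log2). The list passed camera (adjusted p = 2.78e-08; adjusted p = 0.307 with an estimated correlation).

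Mitochondrially encoded genes fell in 8 of 13 members (10 adjusted over the list alone; median -0.19), among them Mt-cyb, of complex III, by 0.30 and the complex I genes Mt-nd4, Mt-nd1 and Mt-nd4l by 0.23, 0.27 and 0.21 (log2). With scaling by library size only 4 members fell. The list passed camera (adjusted p = 0.00138; adjusted p = 0.309 with an estimated correlation), with NMDA 1 (-0.01) within the PBS range of scores. In limma trend on FPKM none of these 4 genes passed (adjusted p up to 0.105, 0.103, 0.0752 and 0.176), and Mt-nd4l did not with the replicate number as a block (0.0516). Nuclear genes of oxidative phosphorylation rose in 5 of 25 members (3 adjusted over the list alone; median 0.06), Sdhd and Sdhb, of complex II, by 0.20 and 0.17, Cox5b, of complex IV, by 0.24, Uqcrh, of complex III, by 0.19 and Ndufs3, of complex I and chosen after its values were seen, by 0.12. With library size only 9 members of that list rose. The call of Uqcrh ended with the replicate number as a block, without PBS 5 and NMDA 3 together and without PBS 2, PBS 4, PBS 5, NMDA 1 or NMDA 2 (adjusted p up to 0.0655), and that of Ndufs3 held only without PBS 1, PBS 4 or NMDA 3 of the 12 fits without 1 library (adjusted p up to 0.101) and ended with DESeq2 and with no filter on low counts. The nuclear list did not pass camera (adjusted p = 0.0781), and it passed with library size only (0.0176), by fry (0.0271) and without PBS 1 (0.0317) or NMDA 3 (0.0346).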

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

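The tests of explanations in this part were chosen only after the results were seen, except the splits of the libraries. Chance is argued against for the 6167 changed genes. The highest of the other splits of the 12 libraries into 6 and 6 gave 1630 genes. The same holds for the 984 genes changed at least 2-fold, where the highest other gave 240. Of 462 possible splits 100 were drawn, the real one included, and only 1 gave as many. Any other split mixes the groups on each side and widens the spread within a side, which by itself lowers its count of genes. These counts therefore do not exclude chance. For the 23 lists chance stays open, since 22 of the 100 splits gave at least as many and the highest other gave 28 lists.

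Ganglion cell markers fell more than rod markers. Dilution of retinal RNA by RNA of other cells would lower both alike, and so would not by itself give this difference. The ganglion score minus the rod score differed between NMDA and PBS by -0.99 (two-sided exact permutation p = 0.00217, the smallest possible). That difference is the flagged pattern itself, so that its p-value is no separate test. Dilution behind a fall shared by both lists, such as that of the rod score (-0.32), was not tested. Carry-over of lens or pigmented tissue is argued against by the 18 ganglion markers that were still lower with either a lens or a melanin covariate (medians -1.32 and -1.25). Loss of ganglion cells and lower expression in surviving cells cannot be told apart: the fold changes of the markers that fell ran from -1.72 (Slc17a6) to -0.67 (Ebf1), a spread of 1.05, and how far each marker is shared with other cells was not measured. A loss of cells after an excitotoxin may account for the pattern, as a hypothesis that counts of cells would test.

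Microglia and macrophage genes rose. Blood left in the vessels is argued against, since their score rose more than that of red blood cell genes by 0.85 (two-sided exact permutation p = 0.0303), with Hba-a2 at 88.5 and 125 CPM and Hbb-b1 at 58.5 and 80.3 CPM with PBS and NMDA. Hba-a2 did not pass (edgeR adjusted p = 0.0534) but passed without PBS 3, NMDA 2 or NMDA 5 (lowest adjusted p = 0.0110), and Hbb-b1 (0.0898) passed without PBS 3 (0.0276). Both passed with the replicate number as a block (adjusted p = 0.0311 and 0.0133) and in DESeq2, and Hba-a2 also with library size only, with the stricter filter and in limma trend on FPKM, so that some rise of red cell transcripts is not excluded. More resident microglia with unchanged expression cannot be told apart from other changes: the score of resting microglia genes differed from that of the other members by -1.52, but these genes were listed after values had been seen and without Cx3cr1, which rose by 1.16 (log2). Monocytes that moved in from blood may contribute: a monocyte score was higher by 2.62 (two-sided exact permutation p = 0.00217), with its most abundant genes Itgal and S100a4 rising from 3.05 to 16.2 and from 4.62 to 13.9 CPM, but resident cells that switch on the same genes cannot be told apart from them, and some of these genes were seen before the list was written.

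The ganglion cell scores of NMDA 1 and NMDA 3 lay nearest to PBS among the NMDA libraries. A mislabelled library or a swap with a PBS library is argued against, since the nearest of their ganglion and amacrine scores lay -4.37 SDs from the mean of the 6 PBS libraries, whereas the PBS libraries lay from -1.34 to 3.00 (PBS 1) SDs from the mean of the other 5. Pigmented tissue is argued against for NMDA 1, whose melanin gene score was the lowest of its group (-2.44), and stays open for NMDA 3, whose score was the highest (2.54), although PBS 5 was also high in melanin genes (2.03) with a ganglion score of -0.01. Less NMDA may have reached these retinas. NMDA 1 or NMDA 3 was the NMDA library nearest to PBS in 20 of the 23 passing lists (14 and 6). The 6 lists of NMDA 3 were all lists that fell, and in none of the 12 lists that rose was NMDA 3 nearest. Its scores for complement (1.28), extracellular matrix (1.71) and endothelial genes (0.51) were the highest of all libraries. A smaller change throughout was therefore not seen in NMDA 3. The dose that reached the retina was not measured, so that a smaller dose cannot be told apart from other differences between the rats. In 22 of the 23 passing lists NMDA 3 still lay outside the PBS range, and NMDA 1 did so in 13.

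Among 480 groups of 6 libraries (406 of single genes and 74 of list scores), 31 held a library whose gap to its nearest neighbour took a larger share of the group's range than Dixon's test allows. Chance alone marks about 1 in 20 groups, here 24. PBS 5 was that library in 12 groups, NMDA 1 in 7 and NMDA 3 in 3. The values that follow are log2 CPM for genes and scores for lists, each with the mean of the other 5 libraries and the gap's share of the range, and no explanation was tested for them.

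In PBS 5, Hhatl was low (3.75 against 4.83, share 0.736), as was Grin2c (4.46 against 5.02, share 0.670). Cd3e was high in the same library (-0.76 against -2.93, share 0.640), as were C1r (5.64 against 4.16, share 0.639), C1s (5.24 against 3.56, share 0.651), RT1-DMa (2.96 against 2.11, share 0.759), Tgfbi (2.67 against 1.24, share 0.707) and Dct (7.58 against 5.58, share 0.718). PBS 5 was also high in the scores of neutrophils (1.53 against -0.31, share 0.691), pericytes (0.82 against -0.16, share 0.810), pigment epithelium (1.02 against -0.20, share 0.651) and cell death (0.29 against -0.06, share 0.679).

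In NMDA 1, Rom1 was high (10.80 against 10.40, share 0.639). Low values were those of Lrat (-1.13 against 0.54, share 0.640), Vim (9.19 against 9.86, share 0.721), Phgdh (5.11 against 5.65, share 0.668), Fosl1 (1.15 against 2.20, share 0.729), Fgfr1 (4.65 against 5.85, share 0.643) and the lens membrane score (-3.74 against 0.29, share 0.661). In NMDA 3, Lox (2.01 against 0.63, share 0.768), Dct (8.22 against 4.68, share 0.727) and the pericyte score (1.16 against -0.11, share 0.675) were high.

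In PBS 3, Pla2g7 (-2.34 against -0.88, share 0.632) and Bmf (5.99 against 6.34, share 0.648) were low, and Lrat (2.22 against 1.11, share 0.866), Pcna (5.63 against 5.48, share 0.662) and Rrh (6.16 against 5.90, share 0.725) were high. PBS 1 was high in Grin1 (7.70 against 7.47, share 0.863) and Sv2a (8.89 against 8.70, share 0.664), PBS 2 low in Mag (-1.52 against -0.33, share 0.653) and PBS 6 high in Cry2 (8.30 against 7.86, share 0.767).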

How the results depend on the processing

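The fits with a melanin covariate, the fit without PBS 5 and NMDA 3, and the permutation test of list scores were chosen after seeing the data; the other alternatives were planned. Over 25 alternatives the count of changed genes (6167) stayed within 1.5 times, from 4565 with the stricter filter to 7103 in limma voom with quality weights, and leaving out 1 library gave 5287 (without NMDA 6) to 6629 (without NMDA 1). Genes changed at least 2-fold (984) numbered 264 with the stricter filter, which tested 10815 genes, and 328 in limma trend on log2(FPKM + 1), against 830 on log2(FPKM + 0.1), so that the low number went with the added constant; leaving out 1 library gave 852 to 1157. The lower genes among them (240) numbered 364 without NMDA 3 and 360 in limma voom with quality weights. Passing lists (23) numbered 0 in camera with an estimated correlation (lowest adjusted p = 0.307), where the cause was not tested, and 23 to 25 when 1 library was left out. With the replicate number as a block, 5593 genes, 960 genes at least 2-fold and 25 lists passed. Equal numbers did not pair the libraries: the correlations of the 6 pairs' deviations ran from -0.19 to 0.15, 2 were over 0.1, and 1 pair correlated best with its own number. Of 203 genes followed singly, 57 of them chosen after their values were seen, 178 kept their direction and side of the threshold in all alternatives that tested them, 25 did not in at least 1, and 0 reversed; 185 kept them in all fits without 1 library. Limma's weights were lowest for NMDA 1 (0.443) and NMDA 3 (0.517). Depth left genes near the filter with few counts: Cd3e had 1 or 2 in each PBS library but PBS 5, which had 13, and S100a9 had 0 in PBS 3, PBS 4 and PBS 6, 1 in PBS 2, 6 in PBS 1 and 22 in PBS 5, so that their fold changes rested on few libraries.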

Other observations

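The tests in this part, and the 9 lists they used, were chosen only after the results were seen. Monocyte genes rose in 10 of 10 members (median 2.60; score difference 2.62, two-sided exact permutation adjusted p = 0.00487 over the 9 lists), and 0 of them stood in the fixed lists. Ccr2, the receptor for Ccl2, rose from 0.259 to 3.55 CPM and Fcnb, a ficolin gene, from 0.0299 to 2.67 CPM (log2 fold changes 3.78 ± 1.00 and 6.16 ± 0.94, edgeR adjusted p = 0.0107 and 0.000399). The log2 fold change of Ccr2 was 5.87 without PBS 5 and 3.14 without NMDA 6, and that of Fcnb was 5.21 without NMDA 6. By comparison, 9 tested genes of resting microglia (of the 10 listed, 5 are also in the microglia and macrophage list) had a median of 0.14 and none rose (score adjusted p = 0.448): P2ry12 fell, and Tmem119 and Gpr34, genes of resident microglia, had log2 fold changes of 0.20 and 0.07. The list was written without Cx3cr1 of the microglia and macrophage list, which rose. The contrast with the monocyte genes therefore does not show that genes of resident microglia stayed level.

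Genes of the visual cycle, which regenerates the light-sensitive pigment, fell in 8 of 9 members and rose in 1 (median -1.14), but 5 of the 9 stood in the fixed lists and had been seen to fall, so that the list gave no separate test. Rrh, an opsin gene of the pigment epithelium, fell by 1.29 and Stra6, a vitamin A transporter gene, by 1.06, and Rdh10, a retinol dehydrogenase gene, rose by 0.41 (log2). The call of Rdh10 held only without PBS 3, NMDA 1 or NMDA 3 of the 12 fits without 1 library (adjusted p up to 0.0933), and ended with the replicate number as a block (adjusted p = 0.118), with a melanin covariate and with no filter on low counts. Of 6 melanin pathway genes none passed (median 0.10, score difference -0.49, adjusted p = 0.5), with Dct at 72.3 and 71.8 CPM and Tyrp1 at 49.3 and 45.3 CPM with PBS and NMDA. These values rested on NMDA 3, whose score was 2.54 against -0.62 to -2.44 in the other NMDA libraries. Without it, Dct had a log2 fold change of -1.45 and passed (adjusted p = 0.0288), and Tyrp1 went from -0.12 to -1.27 and did not pass (adjusted p = 0.125). Without PBS 5, whose score was 2.03, they were at 0.57 and 0.55. Red cell genes had 0 of 5 members that passed (median 0.50, score adjusted p = 0.0668).

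Growth factor genes moved both ways. The cytokine gene Lif and the growth factor gene Fgf2 rose by 1.96 and 1.65, the receptor gene Fgfr1 by 0.91, Cntf, a neurotrophic cytokine gene, by 0.46 and Vgf, a neuropeptide gene, by 0.58, and the neurotrophin receptor genes Ntrk2 and Ntrk3 fell by 0.40 and 0.50 and Vegfa, an angiogenic factor gene, by 0.42 (log2). Over 13 such genes, 4 of them also in the fixed lists, 5 rose and 4 fell (score two-sided exact permutation adjusted p = 0.0668). Clock genes fell in 8 of 17 members and rose in 1 (median -0.14, score adjusted p = 0.00779), with Hlf at -0.45, Cry2 at -0.42 and Bhlhe40 at 0.26. Another 8 members did not pass, among them Nr1d1 at -0.02, Dbp at -0.07, Per2 at 0.11 and Per3 at 0.02. The time of day of collection was not given in the sources used here.

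Genes of amacrine subtypes fell in 7 of 9 members and rose in 1 (median -0.72, score two-sided exact permutation adjusted p = 0.00487). Nos1, of nitric oxide-producing cells, and Cck, a peptide gene, fell by 1.20 and 1.28, and Megf10, a gene of cell spacing, rose by 0.42 (log2). Genes of ganglion cell subtypes fell in 7 of 9 (median -0.84, score adjusted p = 0.00487), with Isl2 at -1.53 and Cartpt, a peptide gene of direction-selective cells, at -1.19. Opn4, the melanopsin gene, and Eomes, a transcription factor gene of the same cells, fell by 0.49 and 0.91. Tbx20, another, did not pass (-0.45, edgeR adjusted p = 0.232) and passed without NMDA 3 (adjusted p = 0.0225).

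The score of Opn4, Eomes and Tbx20, genes of melanopsin ganglion cells, fell less than the ganglion cell score, by 0.67. That melanopsin ganglion cells kept more of their transcripts than other ganglion cells is a hypothesis which this difference prompted and does not test, since the 3 genes were picked after part of their values was seen and neither cell numbers nor expression per cell were measured.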
